A study of Mus musculus with 14 samples.

How the data were processed

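RNA was sequenced from T cells sorted out of mouse tumours. Per the labels' protocols, female C57BL/6 mice of a reporter strain, in which a red fluorescent protein marks cells that express Foxp3, carried subcutaneous AE17-OVA tumours, grown from a mouse mesothelioma line that expresses the model antigen ovalbumin. They received 200 µg of an antibody against PD-L1 (clone MIH5) or an isotype control antibody (clone 2A3) into the peritoneal cavity on day 10, and tumours were taken on day 13. PD-L1 is the ligand of the inhibitory receptor PD-1. Regulatory T cells (Tregs) without surface PD-1, Tregs with PD-1 and other CD4 T cells were sorted on CD4, CD25, the red reporter and PD-1, and libraries were made with Smart-seq2, which amplifies full-length cDNA from small inputs and adds no molecular identifiers.

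The 14 libraries fall into 6 groups. CD4 T cells had 2 isotype and 3 treated libraries, PD-1- Tregs 2 and 2, and PD-1+ Tregs 2 and 3. The series text calls the replicates biological. Which animals or pools they came from is not given in the sources used here, so the p-values measure the spread between these libraries.

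The deposited table holds, per the labels and its header, a raw read count and an RPKM value (reads per kilobase of transcript, scaled to mapped reads) for each of 25124 genes and 14 libraries. The submitters' processing notes name HISAT2 2.0.4, SAMtools, HOMER 3.12, DESeq2 and the genome build mm10. The annotation, the counting settings and the use of strand are not given in the sources used here, so genes that overlap or share sequence with a close copy are uncertain. The authors' RPKM values are a scaled form of their counts. The ratio of count to RPKM of a gene, set against the library's typical ratio, spread by more than 2-fold over libraries for 220 of 12395 genes compared (1.77%), and 290 values had counts but an RPKM of 0, so RPKM served only as an alternative. Gene positions come from a RefSeq table of assembly GRCm38.p6, the same build as mm10.

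Counts were tested as deposited with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr over the 6 groups at its minimum count of 10, which left 13434 genes. Libraries were scaled by TMM, and the quasi-likelihood F-test was run with robust estimation in 1 fit of 6 group means over all 14 libraries. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05, and a gene is said to rise or fall only where it passed. The common biological coefficient of variation was 1.22, and the smallest prior degrees of freedom 4.19. Changes are log2 fold changes ± SE, the SE being the size of the change over the square root of F. Comparisons that span several groups average the log2 means of those groups with equal weight, so a group at 0 can move the fold away from the ratio of mean levels. Levels are CPM (counts scaled to 1e+06 per library), mean ± SD over libraries, without a prior count, from TMM-scaled library sizes. A prior count of 2 was added only for correlations between libraries. Where every library of an arm had 0 counts, the fold is a lower bound against a floor of 3 counts per library, and where an arm held 1 to 3 counts in all, the ratio of the pooled counts, each over its libraries' summed sizes, is given with its 95% counting interval, so it can differ from the ratio of mean levels. Intervals and floors cover counting error only, since amplified reads are not independent molecules.

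Set before the data were examined were the tests, the rule for named genes and 27 gene lists. The 20 lists of T cell biology were Treg identity, Treg suppressive molecules, effector Treg regulators and receptors, resting and central T cell genes, TCR-induced genes, inhibitory receptors, mitosis, DNA replication, type I interferon response, interferon-gamma response, IL-2 receptor and STAT5 genes, Th1 and cytotoxic effector genes, Th2, Th17 and Tfh genes, glycolysis, oxidative phosphorylation, sterol and fatty acid synthesis, homing receptors, and p53 and apoptosis genes. The other 7 held dissociation and stress genes and markers of macrophages and monocytes, dendritic cells with MHC class II, B cells, CD8 T and NK cells, neutrophils and mast cells, and mesothelial tumour and stroma. They had 419 entries, of which 2 were not in the count table and 8 were removed by the filter. Lists were tested with camera (limma 3.58.1) on the normal scores that edgeR makes from the counts, at its preset correlation of 0.01 and again with an estimated correlation, adjusted over the 27 lists. Camera ranks a list against all other genes. Single members are counted over all genes and adjusted over the list alone.

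Genes named are the genes of the sort and the treatment (Cd4, Foxp3, Il2ra, Pdcd1, Cd274, Pdcd1lg2); per comparison the 12 largest rises and falls (6 in the smaller comparisons) among genes past the threshold with a mean of at least 10 CPM in the higher arm and every library of an arm above every library of the other; and up to 4 members per list, those of smallest p. Where no gene passed, the 5 of smallest p per direction are named as not past it. Predicted genes, small RNAs and receptor segments were counted but not named.

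Alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter, only the groups compared, library quality weights in limma-voom, replicate numbers as a block (fixed, or random through statmod 1.5.0), limma on log2 RPKM with 1 or 0.1 added, and leaving out each library. Added after the data were seen were a mean treatment comparison over the 3 cell types, the counts without 3 libraries that hold Y-linked reads, a filter at a mean of 50 CPM, a covariate for the macrophage marker level, and limma-voom without a block. The same steps were tested on simulated counts with 200 genes changed, 100 by 4-fold and 100 by 16-fold. Each simulated gene had 1 spread in all libraries, so the simulation lacks the unequal noise of the real groups. Its wrong calls are therefore not an error rate for the real comparisons. With edgeR, 14% of the 4-fold and 69% of the 16-fold changes were recovered for PD-1+ Tregs (13034 genes tested, 1 wrong call), 5% and 60% for PD-1- Tregs (13004 genes, 1 wrong call), 13% and 57% for CD4 T cells (13022 genes, 2 wrong), 34% and 80% between the Treg types (13042 genes, 3 wrong), 53% and 93% between Tregs and CD4 T cells (13006 genes, 9 wrong), and 60% and 83% for the mean treatment comparison (13031 genes, 5 wrong). DESeq2 recovered 44% and 92% for PD-1+ Tregs with 267 wrong calls, and made 226 to 323 wrong calls over these comparisons. A simulated raised list passed at the preset correlation in PD-1+ Tregs and CD4 T cells and was lost there with an estimated correlation (adjusted p = 0.0722 and 0.0626). In PD-1- Tregs it was missed with both (0.0821 and 0.242). A simulated lowered list passed with both in every comparison, in PD-1- Tregs with 7.24e-07 and 0.00708.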

Results

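Gene expression was measured in 3 T cell populations sorted from AE17-OVA tumours, other CD4 T cells, PD-1- Tregs and PD-1+ Tregs, under anti-PD-L1 or an isotype antibody. Tregs are the Foxp3-expressing CD4 T cells that restrain other T cells. Total counts per library ran from 10638848 to 15030804. At least 1 count was found for 13489 ± 869 genes in CD4 T cells (SD, n = 5), 10610 ± 641 in PD-1+ Tregs (n = 5) and 8496 ± 345 in PD-1- Tregs (n = 4). Between the Treg types the exact two-sided permutation p was 0.0159 (0.0317 adjusted over 8 measures). Libraries of the same cell type correlated with a median r across genes of 0.889 in CD4 T cells, 0.715 in PD-1+ Tregs and 0.612 in PD-1- Tregs. Genes are not independent replicates.

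The genes of the sort were measured first. Il2ra, which encodes CD25, stood at 395 ± 162 CPM in Tregs (n = 9) and 44.7 ± 32.7 in CD4 T cells (n = 5), with no overlap between libraries. Foxp3 stood at 173 ± 39.7 CPM in PD-1- Tregs, 68.8 ± 57.3 in PD-1+ Tregs and 31.3 ± 15.3 in CD4 T cells, and PD-1+ Tregs overlapped CD4 T cells. An isotype PD-1+ library was at 15.9 CPM, below every CD4 library (lowest 16.3), and the lowest treated PD-1+ library at 31.1 against 55.0 in the highest treated CD4 library. Pdcd1, which encodes PD-1, stood at 160 ± 71.8 CPM in PD-1+ Tregs (159.6, n = 5) and 38.5 ± 11.5 in PD-1- Tregs (n = 4). These genes or their reporter were used to sort the cells, so they check the labels and are not findings. By Foxp3 the check did not set PD-1+ Tregs apart from CD4 T cells, while by Il2ra it did. Other CD4 T cells sorted with the PD-1+ Tregs were not tested for, which limits the comparisons of the Treg types.

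Markers of cells outside the gate were present in every population. Summed macrophage and monocyte markers reached 8235 ± 1803 CPM in PD-1+ Tregs, 6865 ± 2444 in CD4 T cells and 1772 ± 259 in PD-1- Tregs. The PD-1+ level was 4.65-fold that of PD-1- Tregs (exact two-sided permutation p = 0.00794, the smallest that 126 assignments allow, 0.0317 adjusted), while PD-1+ Tregs and CD4 T cells were not told apart (exact p = 0.341, adjusted 0.546). Dendritic cell and MHC class II genes summed to 33414 ± 11062 CPM in PD-1+ and 12472 ± 3063 in PD-1- Tregs (exact p = 0.0159, adjusted 0.0317). CD8 T and NK cell markers summed to 105 ± 23.1 and 41.1 ± 41.8 CPM, 2.55-fold (exact p = 0.00794, adjusted 0.0317). B cell markers stood at 228 ± 18.3 CPM in isotype and 73.5 ± 22.6 in treated CD4 T cells, and at 333 ± 146 and 57.4 ± 37.5 in PD-1+ Tregs. The plot of detected genes against macrophage markers shows these library differences.

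**Figure D1:**
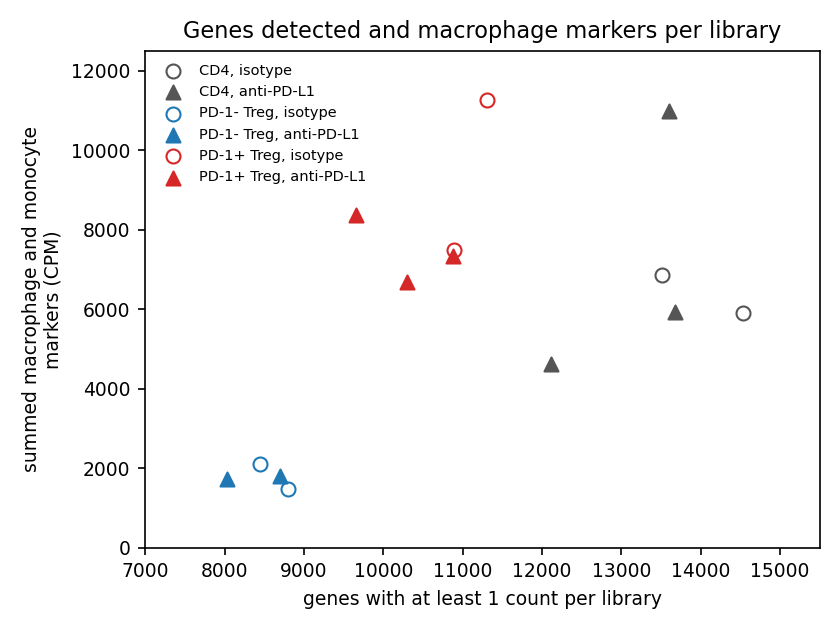
Genes with at least 1 count (x) against summed macrophage and monocyte markers in CPM (y), 1 point per library, 14 in all, with open circles for isotype and triangles for anti-PD-L1. The 4 PD-1- Treg libraries lie lowest on both axes, at 1772 ± 259 CPM against 8235 ± 1803 for PD-1+ Tregs.

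The series title concerns PD-L1 blockade and the suppressive capacity of Tregs, so the treatment was compared within each population, starting with PD-1+ Tregs (3 treated and 2 isotype libraries). Ifngr1, the ligand-binding chain of the interferon-gamma receptor (NCBI gene 15979, chromosome 10, 19591949 to 19610229, GRCm38.p6), rose by 1.93 ± 0.21 on the log2 scale, from 574.1 ± 35.7 to 2192 ± 352 CPM (adjusted p = 0.00564). Igfbp4, a binding protein of insulin-like growth factors and a marker of resting T cells (NCBI gene 16010, chromosome 11, 99040005 to 99052655), fell from 13.7 ± 3.46 to 0.0611 ± 0.0532 CPM (adjusted p = 0.00564). The treated libraries held 2 counts, so the pooled-count ratio of 239.7 has a counting interval of 65.9 to 1988. These were the 2 genes past the threshold in edgeR, with 1083 of 13434 below an unadjusted p of 0.05 against 671.7 by chance. Pdcd1 stood at 100.3 ± 20.8 CPM under isotype and 199 ± 64.9 under treatment, and Foxp3 at 55.3 ± 55.7 and 77.7 ± 68.6, both not past the threshold.

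Gene lists moved more broadly in PD-1+ Tregs. Measures of library quality moved with treatment without overlap in the same libraries. Actb took 4.26% and 3.60% of counts under isotype and 6.47%, 5.88% and 7.27% under treatment, the 10 highest genes 11.3% and 11.4% against 13.6%, 14.3% and 14.9%, and Rn45s 0.209% and 0.255% against 0.117%, 0.146% and 0.0816%. Effector Treg regulators and receptors rose as a list, with 17 of 20 members higher (median log2 change 0.94, adjusted p = 7.52e-06, and 0.0282 with an estimated correlation), and adjusted over the list alone 2 of them rose, the transcription regulator Id2 (1.24 ± 0.25) and the costimulatory receptor Icos (1.29 ± 0.31), against 0 over all genes. Glycolysis genes were higher in 15 of 18 (median 0.60, adjusted p = 4.41e-05, 0.167 with an estimated correlation). The interferon-gamma response (median 0.49, adjusted p = 0.00733, 0.157 with an estimated correlation) had 3 members past the threshold adjusted over the list alone, the interferon-inducible GTPases Gbp7 (1.48), Igtp (0.94) and Iigp1 (2.04). Inhibitory receptors (0.0337, 0.203 with an estimated correlation) had 1, Tigit (1.18 ± 0.31), and homing receptors (0.0183, 0.223) had 1, Selplg (1.35 ± 0.22). Resting and central T cell genes fell as a list (median -0.65, adjusted p = 0.000954, 0.203 with an estimated correlation), with 1 member past the threshold over all genes and 4 falling adjusted over the list alone, Igfbp4, Bcl2 (-3.43), Id3 (-5.82) and Tcf7 (-1.01). Tfh genes fell (median -1.34, 0.000192, 0.138 with an estimated correlation), with Slamf6 (-1.48) and Izumo1r (-1.34) past the threshold adjusted over the list alone, as did oxidative phosphorylation (median -0.29, 0.0125, 0.319) and DNA replication (-0.41, 0.0337, 0.433). Markers of other cells moved with these lists: B cell markers fell (median -2.84, 1.11e-06, 0.0656 with an estimated correlation), while dendritic cell and MHC class II genes (median 0.72, 0.00733, 0.312) and CD8 T and NK markers (median 3.00 with zero arms at their bound, 0.0337, 0.167) rose.

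The calls in PD-1+ Tregs depended on the fit. For Ifngr1 the adjusted p was 0.158 without the first isotype library, 0.104 without the second, 0.722 with only these libraries in the fit and 0.341 with limma-voom, in a range over the alternatives from 1.72e-17 to 0.722, while Igfbp4 kept its call with every single library left out (highest 0.0480) and lost it with only these libraries (0.872, in a range over the alternatives from 1.04e-09). The count of genes was 618 with DESeq2, 149 with limma-voom, 43 and 31 on log2 RPKM with 0.1 or 1 added, 0 with only these libraries, 0 with quality weights, 4 without the 3 Y-linked libraries, and 1 to 4 without the first or the second isotype library.

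In PD-1- Tregs (2 treated and 2 isotype libraries) 358 genes passed the threshold for treatment, 185 up and 173 down. Each gene had 1 spread for all groups, although replicates differed more here than in CD4 T cells. Chi-square per degree of freedom between replicates, which is 1 for counting noise alone, was 332.6 and 460.6 in PD-1- Tregs. In CD4 T cells it was 28.7 to 79.9. The numbers of calls are therefore no measure of which population responded more. Divisions of these 4 libraries that mixed treated and isotype libraries in each arm still called up to 170 genes (median 139.5). Adjusted p-values of single genes in PD-1- Tregs therefore do not hold at face value. Gzmb, the cytotoxic protease granzyme B (NCBI gene 14939, chromosome 14, 56258836 to 56262334), went from 0 counts in both isotype libraries to 240.5 ± 45.1 CPM, at least 873-fold (adjusted p = 0.0149). Cxcr3, a chemokine receptor of type 1 T cells, rose from 3.35 ± 4.61 to 273 ± 71 CPM (6.34 ± 1.09 on the log2 scale). Nkg7, a cytotoxic granule protein, rose by 2.22 ± 0.36, Tigit by 2.14 ± 0.34, and the transcription factor Tox, which chronic antigen signalling induces, by 2.62 ± 0.37. Ifngr1 rose by 2.01 ± 0.22 to 2218 ± 540 CPM (adjusted p = 0.00119). Bach2, a repressor of effector genes, fell from 99.3 ± 94.5 CPM to 0 in both treated libraries, at least 419-fold (adjusted p = 0.00794), and Pdcd1lg2, which encodes the other PD-1 ligand PD-L2, from 40.2 ± 23.3 CPM to 0, at least 169.5-fold (adjusted p = 0.00937).

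Further large rises in PD-1- Tregs started from 0 counts in both isotype libraries. They were the myosin Myo1f (at least 818-fold, adjusted p = 0.000983), the peroxisomal enzyme Phyh (586-fold, 0.000373), Galm (564-fold), Spsb3 (518-fold), the Elongator subunit Elp3 (471-fold), Smim3 (467-fold), Unc5cl (395-fold), Utp6 (394-fold), Strada (394-fold), Elmo2 (371-fold) and Shcbp1 (357-fold), each as a lower bound. Among genes that fell to 0 counts in both treated libraries, again by at least the fold given, were Cnn3 (666-fold, adjusted p = 0.0266), Armc1 (615-fold), Cdk5rap1 (561-fold), Blzf1 (458-fold), the ESCRT-III subunit Chmp2b (457-fold), the syntaxin Stx8 (392-fold), Mmadhc (376-fold), Ormdl1 (374-fold), Zfp277 (367-fold), Rgs16 (343-fold) and Umad1 (342-fold). In 43.0% of the 358 calls an arm was at 0 throughout, 67 of the rises and 87 of the falls. These bounds cover counting error only, not transcripts missed before sequencing, and PD-1- Treg libraries detected the fewest genes. They are therefore no lower bounds of regulation. Under isotype Phyh stood at 63.8 CPM in PD-1+ Tregs and 87.7 in CD4 T cells. Under treatment Armc1 stood at 63.6 and 75.6 CPM in the same cell types. Cd274, which encodes PD-L1, stood at 9.82 ± 13.9 CPM under isotype and 130 ± 34.9 under treatment (129.6, adjusted p = 0.292), and Cd4 at 59.9 ± 56.8 and 228 ± 95.7 (adjusted p = 0.130).

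By list, 7 rose in PD-1- Tregs at the preset correlation and none held with an estimated one. Measures of library quality also moved with treatment in these 4 libraries without overlap. Actb took 6.53% and 8.71% of counts under isotype and 3.16% and 2.74% under treatment, the 10 highest genes 13.2% and 15.4% against 9.19% and 9.54%, and Rn45s 0.213% and 0.130% against 0.318% and 0.368%. Glycolysis led, with 16 of 18 members higher (median 1.13, adjusted p = 2.28e-06, 0.181 with an estimated correlation), 3 past the threshold over all genes, Pkm (1.78 ± 0.27), Ldha (1.54) and Tpi1 (1.26), and 7 adjusted over the list alone. Th1 and cytotoxic effector genes rose (median 2.22 with zero arms at their bound, 0.0302, 0.298 with an estimated correlation), with 4 members over all genes, Nkg7, Cxcr3, Gzmb and the chemokine Ccl3 (at least 143-fold), and 6 rising and 1 falling adjusted over the list alone. Treg suppressive molecules (median 1.34, 0.00216, 0.181 with an estimated correlation) had Tigit and Gzmb past the threshold over all genes and 5 adjusted over the list alone. Homing receptors (median 1.19, 0.00216, 0.209) had 3 by either count, Cxcr3, Selplg (1.19 ± 0.23) and Itgb7 (1.71). The interferon-gamma response (0.00545, 0.181) had Socs1 (2.48) and Igtp (1.28) over all genes and 3 adjusted over the list alone. IL-2 receptor and STAT5 genes (0.0399, 0.181) had Gzmb and Socs1, with 6 rising and 1 falling adjusted over the list alone, and inhibitory receptors (0.033, 0.214) had Tigit by either count. Effector Treg genes missed the threshold as a list (adjusted p = 0.0517), although Cxcr3 and Id2 (1.48 ± 0.27) rose, and among macrophage markers Mrc1 fell at least 153-fold. Summed dendritic cell and MHC class II genes were lower under treatment without overlap (14458 and 15529 CPM against 10985 and 8916). Neutrophil and mast cell markers went from 0 in both isotype libraries to 56.9 and 17.5 CPM.

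The count in PD-1- Tregs depended on what else entered the fit. It was 0 with only these 4 libraries and 0 with library quality weights, 2755 with DESeq2 (357 of the 358 among them), 686 with limma-voom and 690 without the 3 Y-linked libraries. Leaving out 1 library gave 196 (without the second isotype CD4 library) to 1008 (without the first treated PD-1- Treg library).

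CD4 T cells outside the Treg gate (3 treated and 2 isotype libraries) had 1 gene past the threshold, again Ifngr1, which rose by 2.09 ± 0.21 from 416.6 ± 22.8 to 1770.2 ± 267 CPM (adjusted p = 0.00386). Unadjusted p-values below 0.05 numbered 155, against 671.7 by chance. By list, however, 15 passed at the preset correlation and 12 held with an estimated one. Measures of library quality moved here too without overlap, Rn45s from 0.691% and 0.799% of counts under isotype to 0.492%, 0.367% and 0.586% under treatment, and Actb from 3.24% and 3.84% to 3.85%, 6.67% and 4.32%. Effector Treg regulators and receptors were higher in 19 of 20 (median 1.24, adjusted p = 8.04e-27, 6.4e-05 with an estimated correlation), with Id2 (1.71 ± 0.26), the chemokine receptor Ccr8 (1.69) and the costimulatory receptor Tnfrsf4 (1.56) among 6 that rose adjusted over the list alone. Treg identity genes were higher in 13 of 14 (median 1.20, 4.54e-23, 6.4e-05), with Il2ra (2.27 ± 0.45), Capg (1.21) and Tnfrsf18 (1.49) among 7 adjusted over the list alone, and suppressive molecules rose with 3 (median 1.15, 1.27e-12, 0.00436). Th1 and cytotoxic genes were higher in 18 of 20 (median 1.70, 4.29e-14, 0.00423), 2 of them adjusted over the list alone, Nkg7 (2.31 ± 0.34) and the chemokine Ccl5 (2.42). Summed CD8 T and NK cell markers were higher in the same libraries without overlap, at 58.2 and 69.2 CPM under isotype and 71.0, 119 and 90.5 under treatment. Inhibitory receptors rose (median 0.75, 4.55e-06, 0.0141), with Tigit (1.87 ± 0.32) and Pdcd1 (1.65) adjusted over the list alone. None of these members passed over all genes in edgeR, where Ifngr1 was the single call. Each gene's 1 spread also came from the Treg libraries. Chi-square per degree of freedom between replicates was 152.2 to 460.6 there, against 28.7 to 79.9 in CD4 T cells. The low counts of calls and of unadjusted p-values below 0.05 therefore do not show that few genes responded in CD4 T cells.

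Other lists that passed in CD4 T cells included IL-2 receptor and STAT5 genes (median 0.29, adjusted p = 1.05e-09, 0.00117 with an estimated correlation, 4 members adjusted over the list alone), homing receptors (0.83, 5.25e-06, 0.0303, 2 members), glycolysis (0.42, 7.02e-08, 0.0373) and Th17 genes (0.85, 0.00602, 0.0373), all upward. The interferon-gamma response (0.21, 0.0209, 0.103 with an estimated correlation) and dendritic cell and MHC class II genes (0.58, 4.9e-05, 0.115) rose at the preset correlation. Resting and central T cell genes fell, 14 of 15 being lower (median -0.91, 1.27e-11, 0.0141), and so did B cell markers (-1.89, 4.58e-08, 0.0141), mesothelial tumour and stromal markers (-1.01, 4.9e-05, 0.0361) and dissociation and stress genes (-0.29, 0.005, 0.178 with an estimated correlation). Mesothelial markers summed to 1335 ± 262 CPM under isotype and 528 ± 278 under treatment. In the same libraries Foxp3 stood at 18.5 CPM under isotype and 39.8 under treatment, and Il2ra at 13.6 and 65.5. Ifngr1 missed the threshold without either isotype library (adjusted p = 0.155 and 0.218) and with limma-voom (1, the highest of a range from 5.01e-19). The count was 324 with library quality weights, 54 with DESeq2 and 6 with only these libraries in the fit.

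**Figure D2:**
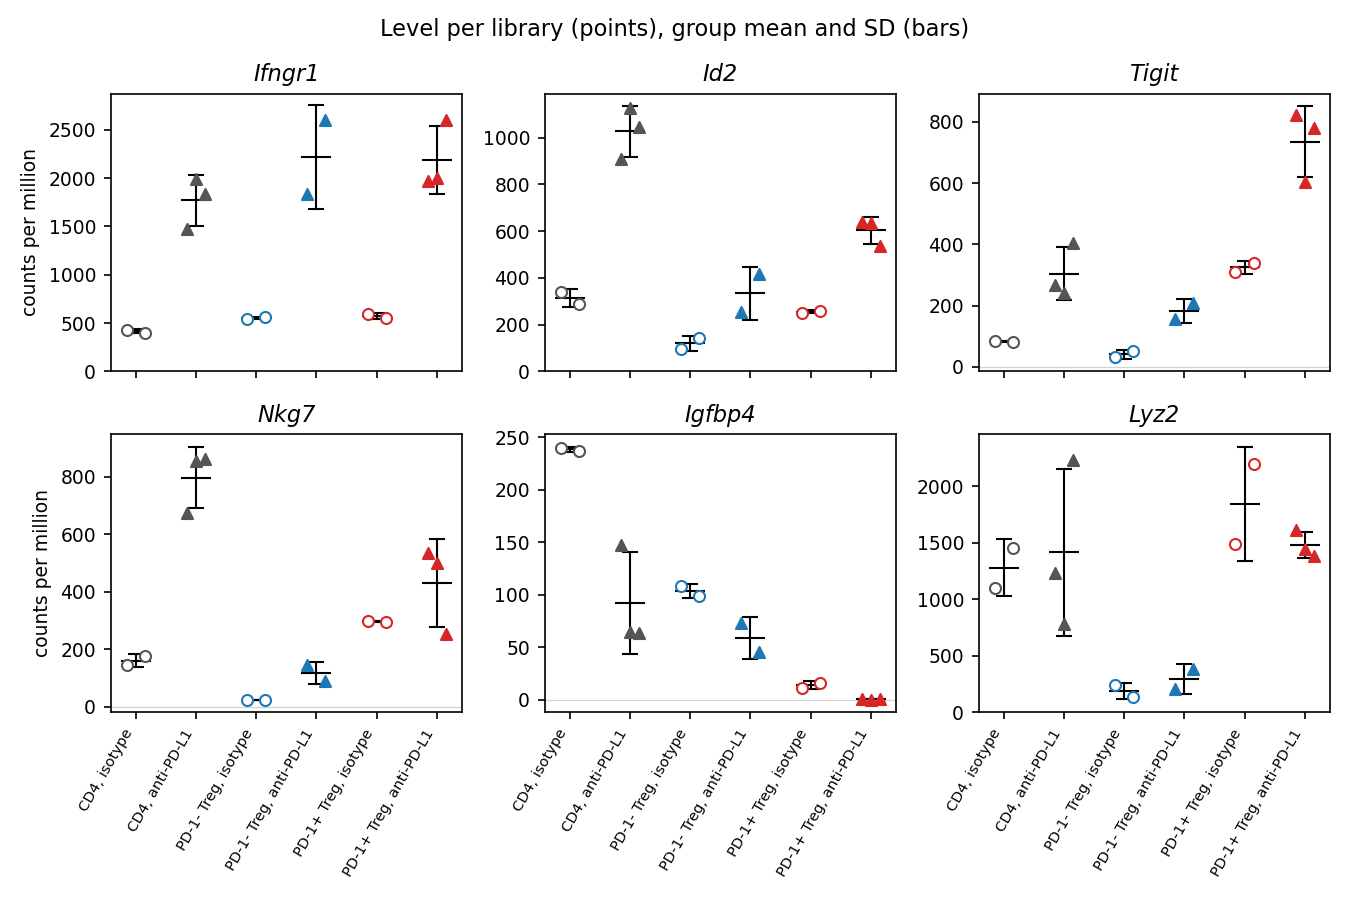
CPM per library (points) with mean and SD (bars) in the 6 groups for Ifngr1, Id2, Tigit, Nkg7, Igfbp4 and Lyz2. Ifngr1 lay at 416.6 to 574.1 CPM on average in the isotype groups and at 1770.2 to 2218 in the treated groups.

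Whether the treatment acted differently between populations was tested directly. Between PD-1+ and PD-1- Tregs the effect differed for 196 genes, 113 toward PD-1+ and 83 toward PD-1- Tregs. With limma on log2 RPKM the balance turned, to 25 and 63 with 1 added and 74 and 128 with 0.1 added. The shares of Actb, the 10 highest genes and Rn45s also moved with treatment in opposite directions in these Treg types. Phyh went from 0 to 161.5 CPM with treatment in PD-1- Tregs and from 63.8 to 61.5 in PD-1+ Tregs (adjusted p = 0.000748), and Galm from 0 to 155 and from 140.6 to 111 (0.00251). In the other direction, Blzf1 went from 109 to 0 CPM in PD-1- and from 11.9 to 59.1 in PD-1+ Tregs (0.00648), Rgs16 from 81.4 to 0 and from 43.8 to 126 (0.00733), and Pdcd1lg2 from 40.2 to 0 and from 21.9 to 70.2 (0.0139). Ifngr1 had a difference of -0.07 ± 0.28, not past the threshold. None of the 27 lists passed (smallest adjusted p = 0.178, for Tfh genes and for dissociation and stress genes). The count was 0 with only these libraries in the fit and 0 with quality weights, 10 with treatment and bracketed title number as a block, 2166 with DESeq2, and 33 (without the first isotype PD-1+ library) to 878 (without the first treated PD-1- library) with 1 library left out.

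Between PD-1+ Tregs and CD4 T cells no gene differed in its response in edgeR (smallest adjusted p = 0.871, 470 genes below an unadjusted p of 0.05 against 671.7 by chance, 274 past the threshold in DESeq2 and 0 in limma-voom). The 5 genes of smallest p per direction, not past the threshold, included the ubiquitin ligase Peli1 (1.20 ± 0.24), Tti1, Golga1, Arid3b and Fpgt on the side of PD-1+ Tregs, and Igfbp4 (-6.27 ± 1.06), Maged2, Nkg7 (-1.78 ± 0.44), Pdlim4 and Tmem8 on the side of CD4 T cells. For 5 lists the treatment effect was lower in PD-1+ Tregs than in CD4 T cells. Treg identity (14 of 14 negative, adjusted p = 4.12e-05, 0.0247 with an estimated correlation), Th1 genes (0.0148, 0.372 with an estimated correlation) and suppressive molecules (0.0463, 0.372) rose in CD4 T cells and were not past the threshold in PD-1+ Tregs. Tfh genes (0.00229, 0.372) fell in PD-1+ Tregs and were not past it in CD4 T cells, and B cell markers (0.0155, 0.372) fell in both, by a median of -2.84 in PD-1+ Tregs and -1.89 in CD4 T cells.

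PD-1+ and PD-1- Tregs were then compared with the treatments averaged (5 and 4 libraries), to describe what sets apart the Tregs that carry the receptor. The inhibitory receptor Tigit stood at 571 ± 239 CPM in PD-1+ and 112 ± 84.7 in PD-1- Tregs, a rise of 2.49 ± 0.24 on the log2 scale (adjusted p = 0.000403). Ccr8, a chemokine receptor of tumour Tregs, stood at 525 ± 181 and 106 ± 31.6 CPM (2.15 ± 0.24), and Nkg7 at 377 ± 131 and 71 ± 57.4 (2.72 ± 0.25). Klf2, a transcription factor of resting T cells (NCBI gene 16598, chromosome 8, 72319062 to 72321654), fell from 184 ± 111 CPM in PD-1- to 33 ± 12.5 in PD-1+ Tregs (-2.35 ± 0.39, adjusted p = 0.00752). In all, 511 genes were higher in PD-1+ Tregs and 64 lower, with a median log2 difference over all genes of 0.42.

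By list, macrophage and monocyte markers moved furthest, with 17 of 17 higher in PD-1+ Tregs, 13 past the threshold over all genes and 17 adjusted over the list alone (median 3.81, adjusted p = 5.55e-20, 0.0408 with an estimated correlation). The complement gene C1qa was at least 809.5-fold higher, Mrc1 7.34 ± 0.78, Lyz2 2.82 ± 0.33 (1628 ± 332 against 241 ± 105 CPM) and Cd14 3.00 ± 0.35. The value for Mrc1 was enlarged by treated PD-1- Tregs at 0. Mrc1 stood at 98.9 CPM in PD-1+ and 36.2 in PD-1- Tregs under isotype, and at 96.1 and 0 under anti-PD-L1. The largest rises by the naming rule each started from 0 counts in PD-1- Tregs. They were the scavenger receptor Msr1 (at least 547-fold), Clec4a3 (483-fold), Pla2g7 (319-fold), Ccl12 (304-fold), Fcrls (294-fold), the condensin subunit Ncapg (265-fold), Gpr160 (227-fold), Gypc (206-fold), Cbr2 (183-fold), the platelet factor Pf4 (176-fold), Adam9 (171-fold) and Gda (166-fold). Dendritic cell and MHC class II genes rose with them (median 1.45, adjusted p = 0.0124, 0.481 with an estimated correlation), 5 by either count, among them Cd74 (1.45), H2-Ab1 (1.37), H2-Aa (1.60) and H2-Eb1 (1.52).

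Among T cell lists, inhibitory receptors rose with 4 members over all genes and 7 adjusted over the list alone, Tigit, Lag3 (from 0.0233 to 43.0 CPM) and Cd244a (at least 129-fold) leading (median 2.08, adjusted p = 0.00174, 0.0691 with an estimated correlation). The list and these counts include Pdcd1 (1.91 ± 0.36), whose difference was set by the sort. Th1 and cytotoxic genes rose with 5 and 9 (median 2.60 with zero arms at their bound, 9.48e-05, 0.0549), led by Nkg7, Ccl5 (2.22), Ccl3 and Cxcr3 (2.87). Effector Treg genes rose with 5 and 6 (median 0.84, 0.00153, 0.0453), including Ccr8, Id2 (0.97) and the costimulatory receptor Tnfrsf9 (1.42). Mitosis genes were higher in 23 of 24, 4 past the threshold over all genes and 11 adjusted over the list alone (median 1.76, 7.58e-08, 0.0774), with Nusap1, Kif11, Birc5 (1.18 ± 0.30) and Bub1. DNA replication had 1 by either count, Pola1 (median 0.71, 0.0168, 0.481). Bub1 and Pola1 each had a PD-1- group at 0 and went the other way in the other treatment. Bub1 stood at 28.3 CPM in PD-1+ and 55.2 in PD-1- Tregs under isotype, and Pola1 at 17.7 and 32.7 under anti-PD-L1. Gzmb, of the Th1 list, did likewise, at 33.4 CPM in PD-1+ and 0 in PD-1- Tregs under isotype and 106 and 240.5 under anti-PD-L1. Ccl3 stood at 43.2 and 0 CPM under isotype but at 41.4 and 39.4 under anti-PD-L1. TCR-induced genes missed as a list (0.255), with Nr4a2 and Egr2 among 4 that rose. The summed macrophage markers were 4.65-fold and the CD8 T and NK cell markers 2.55-fold higher in the same PD-1+ libraries.

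Resting and central T cell genes fell in PD-1+ Tregs, 14 of 15 being lower, 8 past the threshold over all genes and 11 adjusted over the list alone (median -1.87, adjusted p = 2.19e-17, 0.0408 with an estimated correlation). Besides Klf2 they included Igfbp4 (-6.33 ± 0.61) and the egress receptor S1pr1 (-1.90). Treg identity fell slightly as a list (median -0.50, 0.00577, 0.049), with no single member past the threshold in edgeR. Foxp3 stood at 68.8 ± 57.3 and 173 ± 39.7 CPM (adjusted p = 0.187). The interferon-gamma response fell by median (-0.41) and by test (0.000115, 0.0443) while its mean was 0.30, with Gbp2 (-1.66) and Socs1 (-1.72) lower, and IL-2 receptor and STAT5 genes did likewise (median -0.30, mean 0.17, 0.0028, 0.0453), with Socs1 and Ccnd2 (-0.64). Other falls were Klhl2 (-5.22), Nsg2 (-4.22), the chromatin organiser Satb1 (-2.36), Aldh18a1 (-2.03), the sterol regulator Srebf2 (-2.01), Kansl2 (-1.98), the death receptor Tnfrsf25 (-1.93), Ints4 (-1.81) and Ablim1 (-1.76 ± 0.24).

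**Figure D3:**
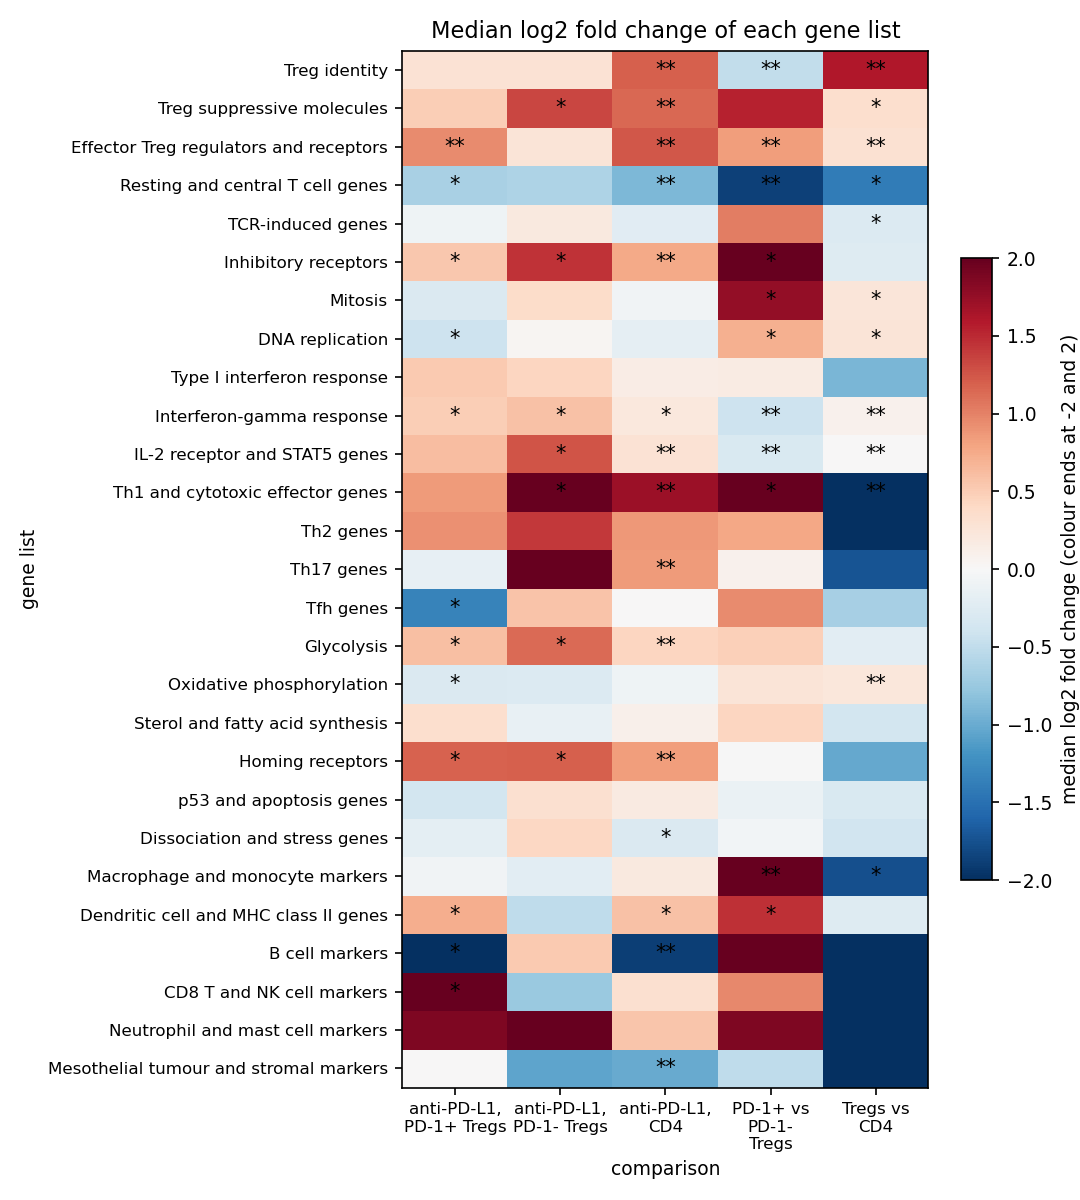
Median log2 fold change of the 27 gene lists (y) in 5 comparisons (x), with colours ending at -2 and 2 and genes with a zero arm at their bound; * marks lists past the threshold with the preset correlation and ** those also past it with an estimated one. Macrophage and monocyte markers had a median of 3.81 between PD-1+ and PD-1- Tregs, and Treg identity 1.61 between Tregs and CD4 T cells.

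In 26.8% of the 575 calls every PD-1- library was at 0. With the macrophage marker level as a covariate, an alternative chosen after the data were seen, no gene passed: the difference of Tigit went from 2.49 to 1.86 and that of S1pr1 from -1.90 to -0.73. With DESeq2 2963 genes passed, with limma-voom 1332, with only these 9 libraries 33, with treatment and bracketed title number as a block 84, with quality weights 1, and with 1 library left out from 281 (without the first isotype CD4 library) to 1301 (without the first treated PD-1- Treg library).

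Within each treatment the Treg types were compared in libraries that share no sample. Under isotype (2 and 2 libraries) 105 genes were higher and 12 lower in PD-1+ Tregs. Clec4a3 (at least 608-fold), Galm (511-fold), Fcrls (481-fold), Ccl12 (417-fold), Msr1 (403-fold) and Ncapg (328-fold) were highest, and Satb1 (-3.26), Klf2 (-2.93), the transcription factor Foxo1 (-2.68), Znrf3 (-2.45) and Zc3hav1 (-1.67) fell. Under anti-PD-L1 (3 and 2 libraries) 197 were higher and 41 lower, with Msr1 (at least 674-fold), Plek (639-fold), Prune2 (614-fold), Rgs16 (533-fold), Mmadhc (478-fold) and App (475-fold) highest. Tapt1 was at least 372-fold and Impad1 at least 123-fold lower, Klhl2 fell by 8.28, and with 1 to 3 counts in the PD-1+ libraries the pooled-count ratios were 1189 for Sp4 (329 to 9829), 1238 for Pdlim4 (222 to 48943) and 1036 for Igfbp4 (286 to 8566). Across 4173 genes, which are not independent replicates, the changes under the 2 treatments correlated with r = 0.22 (Spearman 0.0926). Of the calls, 26 rose in both against 1.54 for independent lists, 2 fell in both against 0.0366, and 1 went opposite ways. The lists were not independent, since 1 fit gave each gene the same spread in both comparisons. The excess is therefore no measure of agreement.

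At the preset correlation 13 lists passed under isotype and 9 under anti-PD-L1. Macrophage markers rose in both (adjusted p = 8.55e-14 and 1.59e-12, 0.0848 and 0.0432 with an estimated correlation), and resting genes fell in both (4.32e-11 and 2.13e-12, 0.0848 and 0.0432). Mitosis rose in both (3.96e-05 and 0.00156, 0.188 and 0.362 with an estimated correlation). Th1 genes passed under isotype (3.22e-05, 0.108) and not under treatment (0.0962, 0.387), and for this list the difference between the treatments did not pass. In 47.0% of the isotype calls and 50.8% of the treated calls an arm was at 0 throughout. With treatment and bracketed title number as a block the counts were 26 and 58, with only the compared libraries in the fit both were 0, with the macrophage covariate both were 0, and with DESeq2 they were 1961 and 2533. Leaving out 1 library gave 47 to 468 under isotype and 115 to 878 under treatment.

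Tregs and other CD4 T cells were compared over both treatments and both Treg types (9 and 5 libraries), as the reference for what marks a Treg in these tumours. Il2ra, which the sort set apart, rose by 3.70 ± 0.32 (adjusted p = 0.00025), the costimulatory receptor Tnfrsf4 from 389 ± 223 to 1706 ± 458 CPM (2.40 ± 0.20) and Ikzf2, the Treg transcription factor Helios, from 113 ± 50.6 to 392 ± 148 (1.93 ± 0.23, adjusted p = 0.00317). Ctla4 rose by 2.06 ± 0.32 and the TGF-beta docking protein Lrrc32 by 3.24 ± 0.79. Some cytotoxic genes were lower in Tregs, with Nkg7 at 241 ± 189 against 543 ± 357 CPM (-1.36 ± 0.19) and the granzyme Gzmk at least 84.5-fold lower. Foxp3 (1.96 ± 0.54, adjusted p = 0.0637) and Cd4 (-1.37 ± 0.34, adjusted p = 0.0515) missed the threshold. In all 43 genes rose and 369 fell, with a median log2 difference over all genes of -0.73.

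By list, Treg identity rose with 13 of 14 members higher, 8 past the threshold over all genes and 11 adjusted over the list alone (median 1.61, adjusted p = 1.6e-25, 8.26e-05 with an estimated correlation). IL-2 receptor and STAT5 genes rose as ranked against other genes (median 0.01, 8.09e-07, 0.00556), with Il2ra, the kinase Pim1 (1.41), Cish (1.79) and Socs2 (2.31) by either count. Effector Treg genes rose (median 0.31, 1.67e-05, 0.0136) with Tnfrsf4 and Tnfrsf9 (1.68) up and Id2 (-1.02) and Cxcr3 (-2.13) down. Oxidative phosphorylation was higher in 32 of 40 (median 0.22, 1.09e-14, 0.0138), with no member past the threshold in edgeR, and the interferon-gamma response rose by test (median 0.09, mean -0.22, 7.45e-05, 0.0238). Suppressive molecules (median 0.34, mean -0.43, 0.000134, 0.057 with an estimated correlation), DNA replication (0.26, 0.00018, 0.23), mitosis (median 0.25, mean -0.36, 0.0143, 0.48) and TCR-induced genes (median -0.28, mean -0.62, 0.00893, 0.23) ranked above other genes at the preset correlation. The test and the mean differed in sign for 4 lists (interferon-gamma, suppressive, mitosis and TCR-induced) and the test and the median for 1 (TCR-induced), with all genes shifted by -0.73.

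Th1 and cytotoxic genes fell in Tregs as a list, 20 of 20 having a negative log2 change, 6 past the threshold over all genes and 13 adjusted over the list alone (median -2.75, adjusted p = 1.73e-06, 0.0353 with an estimated correlation), including the pore-forming Prf1 (-8.31), Gzmk and Fasl (-5.41). For Gzmb and Ccl3 that sign came with isotype PD-1- Tregs at 0. Gzmb stood at 240.5 CPM in treated PD-1- and, isotype first, at 33.4 and 106 in PD-1+ Tregs, against 3.25 and 62.8 in CD4 T cells. Ccl3 stood at 39.4, 43.2 and 41.4 CPM in these Treg groups against 13.1 and 39.7. Resting and central genes fell with 5 and 8 (median -1.40, 0.000686, 0.252 with an estimated correlation), led by Igfbp4 (-4.09), Tcf7 (-1.50), S1pr1 (-1.55) and Lef1 (-1.73), and macrophage markers with 4 and 11 (median -1.75, 9.34e-05, 0.23), their sum being 6865 ± 2444 CPM in CD4 T cells, 1772 ± 259 in PD-1- Tregs and 8235 ± 1803 in PD-1+ Tregs, so that PD-1- Tregs alone were lower. Further rises were Rrn3 (1.00), Samsn1 (0.97), Ppid (0.92), Cyb5a (0.83), Anp32b (0.64) and Nfkbia (0.57). Further falls were Plekhf1 (at least 87.0-fold), Rnf144a (56.0-fold), Rtn4rl1 (49.25-fold), Pou6f1 (42.2-fold), Wnt10a (42.05-fold) and Slc35f5 (-9.60), and with 1 to 3 counts in Tregs Hid1 (pooled-count ratio 2031, 364 to 80297), Ggt1 (1680.0, 301 to 66417), Sema4f (1335, 239 to 52781), Lpar1 (1174, 210 to 46449) and Zfp758 (820.0, 226 to 6780). In 11.7% of the 412 calls every Treg library was at 0, and CD4 libraries detected more genes. The count was 2365 with DESeq2, 2557 with limma-voom, 2263 with quality weights, 48 with treatment and bracketed title number as a block, 209 without the 3 Y-linked libraries, 5 with the macrophage covariate, and 24 (without the first isotype CD4 library) to 1061 (without the first treated PD-1- Treg library) with 1 left out.

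Of the lists, 5 passed in none of the 10 comparisons. Their adjusted p ran from 0.0787 to 0.989 for the type I interferon response, 0.0573 to 0.922 for Th2 genes, 0.257 to 0.936 for sterol and fatty acid synthesis, 0.28 to 0.975 for p53 and apoptosis genes, and 0.32 to 0.989 for neutrophil and mast cell markers. Single members did pass: between PD-1+ and PD-1- Tregs Cdkn1a, the cell cycle inhibitor p21, rose by 1.45 ± 0.26 and the interferon-induced Oasl2 rose from 13.0 ± 16.6 to 56.2 ± 20 CPM, and with treatment in PD-1- Tregs the sterol sensor Insig1 fell by 2.73 (± 0.46).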

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

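The differences in treatment effect were tested as planned; the tests of a larger Treg share, given at the end, were chosen only after the results were seen.

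The treatment effect differed between PD-1+ and PD-1- Tregs by the test of the difference itself (edgeR, adjusted p) for named genes and list members, most of which lay at 0 in an arm of the PD-1- Tregs. Genes that started from 0 counts under isotype in PD-1- Tregs, with a lower treatment effect in PD-1+ Tregs, were Phyh (0.000748), Spsb3 (0.00193), Galm (0.00251), Myo1f (0.00339), Elp3 (0.00733), Pdlim4 (0.00733), Utp6 (0.00744), Strada (0.0118), Elmo2 (0.0132), Zfp212 (0.0155), Shcbp1 (0.0193), Clu (0.0351), Smim3 (0.0351), Ccl3 (0.0374), Unc5cl (0.0415), Gzmb (0.0444) and Pola1 (0.04999). For Gzmb, levels went from 0 to 240.5 CPM in PD-1- and from 33.4 to 106 CPM in PD-1+ Tregs, so that both means were higher under treatment. Means in PD-1+ Tregs were also higher under treatment for Spsb3 (29.97 to 70.4 CPM, without overlap of libraries), Myo1f (83.0 to 171), Strada (32.7 to 50.9), Elmo2 (32.3 to 44.6), Unc5cl (22.8 to 30.4), Shcbp1 (63.2 to 66.4) and Elp3 (57.1 to 58.7). For Clu they went from 0 to 44.9 and from 19.4 to 0 CPM, and for Pdlim4 from 0 to 35.9 and from 18.8 to 0.0325 CPM. Genes that went to 0, or for Cdon to 0.037 CPM, under treatment in PD-1- Tregs were Armc1 (0.00153), Mmadhc (0.00193), Blzf1 (0.00648), Mrc1 (0.00728), Rgs16 (0.00733), Stx8 (0.00733), Chmp2b (0.00835), Ormdl1 (0.00835), Rbm43 (0.00958), Zfp277 (0.0107), Qk (0.0126), Pdcd1lg2 (0.0139), Bach2 (0.0153), Oasl2 (0.0180), Umad1 (0.0180), Bub1 (0.0246), Cdon (0.0246), Cdk5rap1 (0.0373) and the kinase gene Syk (0.0395). Bach2 stood at 99.3 and 0 CPM in PD-1- Tregs and at 9.31 and 14 CPM in PD-1+ Tregs, isotype first, and Syk at 46.8 and 0 against 9.95 and 51.8. The difference for Igfbp4 had an adjusted p of 0.0107, its mean falling from 103 to 58.9 CPM in PD-1- and from 13.7 to 0.0611 CPM in PD-1+ Tregs. List members without a 0 arm were Nfatc1 (0.0107), from 24.4 to 183 CPM in PD-1- and from 183 to 85.0 in PD-1+ Tregs, Insig1 (0.0207), from 342 to 51.6 and from 148 to 219, Il2rg (0.0319), from 5994 to 3598 and from 2844 to 4518, and Tox (0.0351), from 55.6 to 341 and from 276 to 331. None of these differences passed with only the Treg libraries in the fit, where the count was 0. No biological explanation of them was tested.

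The lists with a lower treatment effect in PD-1+ Tregs than in CD4 T cells were Treg identity (adjusted p = 4.12e-05, 0.0247 with an estimated correlation), Tfh genes (0.00229), Th1 and cytotoxic genes (0.0148), B cell markers (0.0155) and Treg suppressive molecules (0.0463), the last 4 at 0.372 with an estimated correlation. Tfh genes and B cell markers are lists that fell in PD-1+ Tregs, so for them the lower effect is the larger fall. In CD4 T cells the Treg identity list rose by a median of 1.20, and more Tregs among the sorted CD4 T cells under treatment could give such a rise, although the sort on CD25 and the red Foxp3 reporter should remove them. With the share set by Foxp3, 18.1% of Treg RNA under isotype and 29.1% under treatment, the other Treg identity genes rose by a median of 2.05 times what that share predicts, or 1.96 times with PD-1- Tregs as the reference (shares of 12.4% and 20.3%) and 1.20 times with PD-1+ Tregs (33.5% and 51.2%), which leaves this explanation open beside a change in the CD4 T cells themselves. The tables argue against it for the Th1 and cytotoxic genes, since 7 of 20 members, 35% against 0.581% of all genes, were higher in every treated CD4 library than in every Treg library and every isotype CD4 library. Those were Tbx21, Ifng, Cxcr3, Cxcr6, Gzmk, Nkg7 and Fasl. CD8 T and NK cell markers, of cells that express such genes too, were also higher in each treated CD4 library (71.0 to 119 CPM) than in the isotype ones (58.2 and 69.2). No other explanation of their rise was tested.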

How the results depend on the processing

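Chosen only after the data were seen were limma-voom without a block, the filter at a mean of 50 CPM, the macrophage covariate, the fits without the 3 Y-linked libraries and the mean treatment effect; the other alternatives were planned. The numbers of genes called rest on 2 to 3 libraries per group and on PD-1- Treg libraries in which many genes had 0 counts, and each comparison borrowed its spread from all 14 libraries. Named genes and lists were followed per comparison, each counting once in every comparison it was followed in. This made 219 gene results and 74 list results, which are not distinct genes or lists. Of 2858 values of the gene results under the alternatives 2020 kept their direction and their side of the threshold, as did 895 of 1039 values of the list results. With 1 library left out it was 2371 of 3066 and 955 of 1036. With DESeq2's size factors in edgeR 215 of the gene results and 74 of the list results did so, with no filter 207 and 73, and with the estimated correlation 36 of 74 list results. The reported counts were 2 for treatment in PD-1+ Tregs, 358 in PD-1- Tregs, 1 in CD4 T cells, 575 between the Treg types, 117 under isotype alone, 238 under anti-PD-L1 alone, 412 between Tregs and CD4 T cells, 196 for the treatment difference between the Treg types, 0 for that between PD-1+ Tregs and CD4 T cells and 165 for the mean treatment effect. Where a count below differs from these, the cause was not tested, except that only the compared groups, left-out libraries and the 50 CPM filter enter fewer libraries or genes by construction. A fit of only the compared groups gave no separate value for Tregs against CD4 T cells or for the mean treatment effect, which hold all groups already.

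Treatment counts in PD-1+ Tregs, PD-1- Tregs and CD4 T cells were 618, 2755 and 54 with DESeq2; 149, 686 and 0 with limma-voom; 0, 0 and 324 with quality weights; 0, 0 and 6 with only the compared groups; and 4, 690 and 2 without the Y-linked libraries. On log2 RPKM with 0.1 added they were 43, 589 and 3, with 1 added 31 and 539 in the Treg types, and without the filter 3 in CD4 T cells.

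Between the Treg types, over both treatments, under isotype and under anti-PD-L1, the counts were 2963, 1961 and 2533 with DESeq2; 1332, 852 and 807 with limma-voom; 1, 0 and 0 with quality weights; 33, 0 and 0 with only the compared groups; and 0, 0 and 0 with the macrophage covariate. They were 284 and 418 within isotype and anti-PD-L1 on log2 RPKM with 1 added, 424 and 538 with 0.1 added, 222 and 154 over both and under anti-PD-L1 with the 50 CPM filter, and 329 under isotype without the Y-linked libraries. With the covariate Birc5 turned to -0.12 (adjusted p = 1, in a range over its alternatives from 0.00112 to 1), and the dendritic cell and MHC class II list turned downward with an adjusted p of 0.661.

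Between Tregs and CD4 T cells DESeq2 gave 2365, limma-voom 2557, quality weights 2263, RPKM with 0.1 added 692, the 50 CPM filter 114, the fit without the Y-linked libraries 209 and the covariate 5. The treatment difference between the Treg types gave 2166 with DESeq2, 399 with limma-voom, 0 with quality weights, 0 with only the compared groups, 88 on RPKM with 1 added, 112 with the 50 CPM filter, 413 without the Y-linked libraries and 94 with the covariate. That between PD-1+ Tregs and CD4 T cells gave 274 with DESeq2. For the mean treatment effect the counts were 1898 with DESeq2, 353 with limma-voom, 4 with quality weights, 103 on RPKM with 1 added, 367 without the Y-linked libraries and 89 with the covariate. On log2 RPKM in limma, where the scaling, the test and the added value all differ from edgeR's, the shares of higher and lower genes moved: with 1 added 334 rose and 205 fell with treatment in PD-1- Tregs against 185 and 173 in edgeR, and 304 and 114 against 197 and 41 between the Treg types under anti-PD-L1. For the treatment difference between the Treg types it was 25 and 63 with 1 added and 74 and 128 with 0.1 added, against 113 and 83.

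Whether the bracketed number pairs the libraries by mouse stays open. The 3 libraries numbered 3 in brackets all held Y-linked counts, 2767 to 2966, against 0 to 1 in the other 11, which ties these 3 to a shared source, and nothing here shows the same of the other numbers. Over 13 pairs with the same bracketed number the deviations from group means correlated at most 0.0615, and at most 0.0506 with the same title number (4173 genes), none over 0.1, while 1 of 20 pairs with different numbers reached 0.134, and the consensus correlation was -0.01. The pairs among the 3 Y-linked libraries, which share a source, gave 0.0506, 0.0395 and -0.0407, so these correlations cannot show or exclude a shared mouse. In groups of 2 the deviations mirror each other, so the pairs are not independent. With the title number as a replicate block the counts were 1 in PD-1+ and 146 in PD-1- Tregs for treatment, 173, 37 and 73 between the Treg types over both, under isotype and under anti-PD-L1, 52 between Tregs and CD4 T cells, 32 for the treatment difference between the Treg types and 29 for the mean treatment effect. With treatment and bracketed number as the block they were 84, 26 and 58 between the Treg types, 48 between Tregs and CD4 T cells and 10 for the treatment difference. This block could not give a treatment effect. Why calls were lost under a block was not tested. As a random effect in limma-voom the block gave 148, 685 and 0 for treatment in PD-1+ Tregs, PD-1- Tregs and CD4 T cells, 1305, 844 and 800 between the Treg types, 2512 between Tregs and CD4 T cells, 398 for the treatment difference and 370 for the mean effect.

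With 1 library left out, the lone library of a group of 2 being assumed to vary like the others, counts ran from 1 to 4 for treatment in PD-1+ Tregs, 196 to 1008 in PD-1- Tregs, 0 to 2 in CD4 T cells, 281 to 1301 between the Treg types, 47 to 468 under isotype, 115 to 878 under anti-PD-L1, 24 to 1061 between Tregs and CD4 T cells, 33 to 878 for the treatment difference between the Treg types, 0 to 3 for that between PD-1+ Tregs and CD4 T cells and 33 to 763 for the mean effect. In PD-1+ Tregs the count was 1 without the first and 4 without the second isotype library, 3 without the first treated library and 3 without either treated PD-1- library. Treatment in PD-1- Tregs had 197 and 196 calls without the first and second isotype CD4 library and 224 and 233 without replicates 1 and 3 of the treated ones, against 609 and 824 without its own isotype libraries and 1008 and 789 without its treated ones. In CD4 T cells the count was 0 without either isotype library, and 2 without treated PD-1- library 1 or treated PD-1+ library 3. The Treg types had 281 and 282 calls without the isotype CD4 libraries, 303, 337 and 309 without the treated ones, 346 and 318 without the isotype PD-1+ libraries, and 1301 and 871 without the first treated and second isotype PD-1- library. Under isotype this was 47 and 54, 59, 76 and 62, 53 and 47, and for the PD-1- libraries 264, 450, 455 and 468, isotype first. Under anti-PD-L1 it was 120 and 115, 138, 150 and 133 without CD4 libraries, and 514, 514, 878 and 405 without PD-1- libraries. Tregs against CD4 T cells had 24 and 27 calls without the isotype and 48, 82 and 49 without the treated CD4 libraries, 52 and 93 without the isotype and 765 without the second treated PD-1+ library, and 1061 and 689 without the first treated and second isotype PD-1- library. The treatment difference between the Treg types had 88 and 89, 98, 117 and 97 without CD4 libraries, 33 and 50 without the isotype PD-1+ libraries and 459, 569, 878 and 568 without PD-1- libraries, and the mean effect 33 and 33, 73, 90 and 71, then 63 and 77, then 437, 588, 763 and 478 for the same libraries. The difference between PD-1+ Tregs and CD4 T cells had 3 calls without the second isotype PD-1+ library, and the mitosis list turned downward between Tregs and CD4 T cells (adjusted p = 0.863) without the first treated PD-1- library, in a range over the left-out libraries from 0.00162 to 0.863.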

Other observations

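The comparison of treatment averaged over the 3 cell types, and every test in this part apart from the planned splits of the libraries, the neighbours of Ifngr1 and the ratios of macrophage markers, was chosen only after results had been seen.

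Averaged over the 3 cell types (8 treated and 6 isotype libraries), 97 genes rose with anti-PD-L1 and 68 fell. The test took these libraries as independent, although those of different cell types may share a mouse, so its p-values can be too small. Treatment and bracketed title number as a fixed block could not give this effect, so the alternatives run for it do not include that block. Ifngr1 rose by 2.01 ± 0.12 on the log2 scale, from 514 ± 78.7 to 2040.1 ± 384 CPM, above every isotype library in each treated one (adjusted p = 1.33e-05), and kept its call in each alternative run (highest adjusted p 0.0397). The other rises that met the naming rule were Gzmb (6.83 ± 1.10), Rbbp8 (5.35), Cxcr3 (3.33 ± 0.53), the triglyceride synthesis enzyme Dgat1 (2.31), Pld3 (2.09 ± 0.21), the glucocorticoid receptor Nr3c1 (1.73), the interferon-inducible surface protein Ly6a (1.53 ± 0.16), the hypoxia factor Hif1a (1.53), Icos (1.25 ± 0.18), Igtp (0.83) and Arl6ip1 (0.58), and the ribosomal protein gene Rps14 fell (-0.56 ± 0.12, adjusted p = 0.0458). Icos went from 159 to 388 CPM in CD4 T cells, from 245 to 544 in PD-1- and from 227 to 556 in PD-1+ Tregs. Hif1a went from 239 to 426, from 69.8 to 359 and from 190 to 498 CPM in the same order.

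By list, 12 passed in this average and 10 held with an estimated correlation. Glycolysis was higher in 17 of 18 (median 0.77, adjusted p = 1.09e-11, 0.0243 with an estimated correlation), with Pkm (0.90) and Tpi1 (0.89) over all genes and 13 adjusted over the list alone. Effector Treg genes rose with 3 and 9 (2.81e-10, 0.00482), among them Id2 (1.48 ± 0.15), and suppressive molecules with 4 and 5 (1.08e-06, 0.0243), Tigit (1.73 ± 0.19), Icos, Gzmb and Lgals1 (0.66). Th1 and cytotoxic genes rose with 5 and 8 (2.78e-06, 0.0332), including Nkg7 (1.69 ± 0.20) and Ccl5 (1.81 ± 0.27), homing receptors with 2 and 7 (2.46e-06, 0.0332), with Selplg (1.12 ± 0.13), and the interferon-gamma response with 1 and 2 (2.28e-05, 0.0243). IL-2 receptor and STAT5 genes (9.55e-06, 0.0126), inhibitory receptors (0.000297, 0.0332) and Treg identity (0.000718, 0.0243) rose as well. Resting and central genes were lower in 14 of 15, 2 and 7 falling (1.58e-06, 0.0458), with Igfbp4 and Bach2 among them. Oxidative phosphorylation (0.019, 0.395 with an estimated correlation) and B cell markers (0.04, 0.339) fell at the preset correlation. Leaving out 1 library gave 33 (without either isotype CD4 library) to 763 calls (without the first treated PD-1- Treg library), and quality weights gave 4.

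Ifngr1 rose with treatment in each of the 3 cell types. Against a genome stretch that differs between the treated and the isotype mice speaks that 5 of 33 tested neighbours within 5 Mb had a p under 0.05, 1.02 times the share of other genes (95% interval 0.345 to 2.15), and 0 of them an adjusted p under 0.05 in edgeR. Against RNA of macrophages speaks that the log2 rise was 2.01 ± 0.22 in PD-1- Tregs, where macrophage markers were lowest, and 1.93 ± 0.21 in PD-1+ Tregs. Against the 3 treated libraries with Y-linked reads as the source speaks a log2 rise of 1.76 in PD-1+ Tregs without them, within 1 SE of the 1.93 with them. A response of the cells to PD-L1 blockade may be the cause, as a hypothesis.

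Macrophage genes were higher in PD-1+ than in PD-1- Tregs, although the sort was on CD4. Fewer detected genes in PD-1- libraries did not account for it: the 8 of 17 markers with at least 10 counts in every PD-1- library differed by a median log2 of 1.78 (0.987 to 4.87). The SD over these markers divided by the square root of their number was 0.46, which is no error over libraries. The markers kept the ratios they have in CD4 libraries (Spearman 0.971 over markers, median absolute log2 deviation from 1 factor 0.124), as RNA of macrophages would, and this explanation, likely for these markers, was among those whose test was set before its result. For the T cell genes that were higher in PD-1+ Tregs it stays open. The 9 called effector Treg and inhibitory receptor genes lay a median log2 of 0.79 above their level in CD4 T cells, whose macrophage level was as high. The SD over these genes divided by the square root of their number was 0.41. Of the 9, 7 were higher, while Cxcr3 (-0.74) and Id2 (-0.68) were lower. Pdcd1 among them was set by the sort, and Tnfrsf9 was higher in Tregs as a whole, so this comparison cannot decide the question. With the macrophage level as a covariate the calls ended mainly through wider errors, Tigit going from 2.49 ± 0.24 to 1.86 ± 0.71 and Nkg7 from 2.72 ± 0.25 to 2.80 ± 0.76, while S1pr1 went from -1.90 ± 0.30 to -0.73 ± 0.94 and Lyz2 from 2.82 ± 0.33 to 0.42 ± 0.62.

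Other divisions of the libraries were counted for each comparison. For the Treg types the planned model held treatment plus cell type over 9 libraries. There 2 of 60 divisions drawn, the real one included, gave as many as its 12 genes. This share is under 0.05, but the highest other gave 138 genes, so the count alone does not exclude chance. That division set the 4 isotype libraries and 1 treated PD-1- library against the other treated ones. Since the model holds treatment, that division rests on 1 treated PD-1- library against the other treated ones. Its count can follow from that 1 library and shows no structure of the samples. With all 14 libraries in the fit, only the real division of 60 gave as many as the 575 genes. The highest other gave 196, from exchanging the isotype Treg types, which is the test of the treatment difference between the Treg types. This version was added after the planned one had left chance open, and it took libraries as independent, so it does not exclude chance either. For Tregs against CD4 T cells chance was excluded for the 23 genes of the planned additive model (1 of 60, highest other 5), with libraries taken as independent. For the mean treatment effect 1 of 60 divisions, the real one, gave as many as its 165 genes (highest other 106, median of the others 59). Those divisions exchanged treatment labels within each cell type as if all libraries were independent. Libraries of different cell types may share a mouse, as the 3 with Y-linked counts share a source, so chance is not excluded there. Within single cell types the divisions are too few for a share under 0.05: the real value and highest other were 2 and 1 genes in PD-1+ Tregs (10 divisions), 358 and 170 in PD-1- Tregs (3 divisions) and 1 and 0 in CD4 T cells (10 divisions).

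Y-linked genes had 2767, 2966 and 2929 counts in 3 treated libraries, 1 of each cell type with the same bracketed number in its title, and 0 to 1 in the other 11, although the labels say that the mice were female. Xist stood at 17.9, 59.9 and 0.974 CPM in those 3 libraries and at 104 to 668 in the others.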
